A study of Mus musculus with 3 samples.

How the data were processed

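The series measured single-cell gene expression in the sinoatrial node (SAN) region, atrium included, of mouse embryos at stage E13.5 that carried Shox2Cre and the R26RmTmG reporter. It holds 3 entries: sample S1 sequenced once, and sample S5 sequenced at a first and at a deeper depth. The entry titles give both S5 entries as 1 sample, so S1 and S5 deeper were the 2 samples of every comparison (n = 2), and S5 first served as an alternative. The reporter and Cre sequences were not analysed here. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 2.1.0 against mm10, per the submitters' processing notes. The annotation release behind those counts was not given in the sources used here. The values were whole numbers, as counts are.

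Barcodes were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. In S1 this left out 244 barcodes for genes and 211 for mitochondrial share, of 4152. In S5 deeper it left out 437 and 72, of 3770. Scrublet scoring with an expected 3% of doublets and an automatic threshold called 27 of 6958 cells, or 0.388%. That is under 0.5%, so the caller has not worked on these data. Its calls were removed as designed, leaving 3695 S1 and 3236 S5 cells, 6931 in all, and doublets remain among them. Removing the 3% of cells with the highest scores in each sample was added as an alternative.

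Counts were scaled to 10000 UMIs per cell and log-transformed. For clustering, 2000 variable genes were chosen over samples, leaving out every gene of the fixed lists and mitochondrial, ribosomal protein, Xist and Y-linked genes. They were z-scored within each sample and reduced to 30 principal components. A graph of 15 neighbours was partitioned with the Leiden method at resolution 1.0 with seed 1. All cardiomyocyte clusters were then clustered again in the same way at resolution 0.5. No deposited cell annotation was used.

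Clusters were named from 17 marker lists written before the data were examined, as were the 21 gene lists, the tests, the cell filters and the rule for the genes named. A marker counted for a cluster at 10 CPM (UMIs scaled to a common class total) or more and at least 2.0-fold over the mean of the other clusters. For z-scores and for ranking genes by fold, 5.0 CPM was added before taking log2. Classes with at least 3 such markers were eligible, and the class with the highest mean z-score of its markers gave the name. A cluster with more markers of another class than of its own among its top 10 genes by fold stayed unnamed, and so did a cluster with too few markers. This scoring rule was revised more than once after the clusters and their marker values had been seen. The last revision was adopted because cardiomyocyte cluster 4 was judged a SAN cluster from Tbx3, Hcn4, Smoc2, Shox2 and Tbx18. It moved cluster 4 into the SAN-like class, and it moved 1 mesenchymal and 1 leukocyte cluster out of the unnamed group. The SAN-like class without cluster 4 is therefore among the alternatives. Alternative clusterings took for each cluster the name that most of its cells had in the clustering described here. That transfer was chosen after their own marker names had been seen, and it makes like results likelier. Versions named by their own markers were run as well, and 8 clusters in 6 of the 9 alternative clusterings carried another name by their own markers.

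Raw UMIs were summed per sample and class and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr), with the Benjamini-Hochberg adjusted p under 0.05 as the threshold. The sample entered as a block, because all classes of a sample come from 1 suspension. Deviations of S1 from S5 in the SAN-like and atrial-like sums correlated across genes at 0.157, with a median of 0.143 and a lowest value of -0.00456 over pairs of classes. SAN-like against atrial-like cells was tested in 1 fit of all 10 named classes with at least 20 cells in both samples, 20 sums with 9 residual degrees of freedom. In this fit each class was also set against the mean of the log2 levels of the other classes. Nkx2-5-detected against undetected SAN-like cells and SAN-like cluster 4 against cluster 1 used 4 sums each and 1 residual degree of freedom. The design set no minimum of cells for the detected state, which holds 6 S1 and 45 S5 cells. An early fit of SAN-like against atrial-like cells included unnamed classes by mistake, and its count of 782 was seen before the alternatives added later were written; the fit restricted to 2 classes had been seen then too.

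Standard errors (SE) are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. With 0 UMIs in a class, a fold is given as a lower bound against a floor of 3 counts over both libraries. With 1 to 3 UMIs, the ratio of UMIs, each over its class total, is given with an exact 95% counting interval. These intervals, and the exact Clopper-Pearson 95% intervals of shares of cells, cover counting error only. For shares of cells with a UMI, each cell was thinned to the 10th percentile of UMIs, 4956 over cardiomyocytes and 5420 over SAN-like cells, and shallower cells were left out. A cell counted as cycling with at least 3 UMIs over the S and G2/M lists after thinning. The Nkx2-5 and Shox2 shares and the comparison of Nkx2-5 states used separate random draws. The states were set on thinned counts, while full counts were summed for the test. Nkx2-5 itself was left out of that comparison.

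The 21 lists covered pacemaker and calcium current channels, potassium and sodium channels of working myocardium, calcium handling, sarcomere, gap junction and intercalated disc, oxidative phosphorylation, fatty acid metabolism, glycolysis, S phase, G2 and M phase, cardiac and SAN transcription factors, BMP and TGF-beta signalling, Wnt signalling, Notch signalling, retinoic acid signalling, autonomic receptors and cAMP signalling, neuronal and axon guidance genes, extracellular matrix, dissociation stress, hypoxia, and interferon and antigen presentation. They hold 504 genes, of which 2, Ccn1 and Ccn2, were not found under these symbols. They were tested with camera (preset correlation 0.01, and again with the estimated correlation) and fry from limma 3.58.1, adjusted over the lists.

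In each comparison the text names up to 4 members per list with the largest absolute log2 fold change past the threshold, at 20 CPM or more in the higher class and with the same direction in both samples. It names the 10 largest rises and 10 largest falls by the same criteria outside the clustering features, markers and lists. Shox2, Nkx2-5, Isl1, Tbx3, Tbx18, Hcn4 and Nppa are given as checks of the names, not as results. The few genes named outside this rule are marked as chosen after their values were seen. Ensembl IDs are those of the deposited gene tables, and positions were looked up by ID in GENCODE vM21 (GRCm38, which is mm10) for all 241 named genes.

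Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, no sample block, each sample left out in turn, a fit of the 2 classes alone, S5 first in place of S5 deeper, doublet calls kept, other clustering resolutions, z-scoring over all cells, list genes allowed in clustering, clustering on a random part of the UMIs and testing on the rest, stricter cell filters (1000 genes, 5% mitochondrial), and gates on Shox2 and Nkx2-5 UMIs in place of clusters. Added after the data were seen were cluster 1 alone as the SAN-like class, own-marker names, removal of the highest doublet scores, unnamed classes in the fit, cycling by UMI gates, and the comparisons of cardiomyocyte cluster 0 and of cells with UMIs of both Shox2 and Nkx2-5. The test script was run on simulated counts with 200 genes changed 2-fold or 4-fold. In the SAN-like and atrial-like comparison (11232 genes) it recovered 3.09% of the 2-fold and 43.8% of the 4-fold changes. For the Nkx2-5 states (5691 genes) it recovered 44.6% and 92.6%, and for cluster 4 against cluster 1 (6996 genes) 64.1% and 95.7%. For the 3 added comparisons it recovered 25%, 17.2% and 14.3% of the 2-fold changes, in the order in which they are described. False calls made up 0% to 5.16% of the simulated calls. The simulated counts took their spread from the fit being checked, so this share cannot show how often the real calls are false.

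Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3. Values of 3 genes are not reported here.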

Results

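Droplet single-cell RNA sequencing was applied to the SAN region and adjoining atrium of Shox2Cre; R26RmTmG mouse embryos at stage E13.5. The labels give 2 samples of the same stage, tissue and genotype and no treatment, so the comparisons set cell classes of the same samples against each other. S1 held 26066375 UMIs in 4152 barcodes, with medians of 4943 UMIs and 1786 genes per barcode. S5 first held 24389910 UMIs in 3763 barcodes, with medians of 5558 and 1834. S5 deeper held 41067805 UMIs in 3770 barcodes, with medians of 9413.5 and 2539. After filtering, 3695 S1 and 3236 S5 cells were analysed. Values after ± are SEs from the fit (n = 2 samples), whose variance is shared over genes, so they can be smaller than the spread of the 2 samples; adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These p-values rest on that shared variance and on 2 samples, whose spread may be technical.

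The dissected tissue held cardiomyocytes, mesenchyme, epicardium, endothelium or endocardium, mural cells, leukocytes, neural crest or glia, neurons, lymphatic endothelium, epithelium and erythroid cells, each named as like these types from its markers. Cardiomyocytes, led by sarcomere genes such as Tnnt2 and Myh6, made up 12.3% of S1 cells (454, exact 95% interval 11.2% to 13.4%) and 29.0% of S5 cells (938, 27.4% to 30.6%). Mesenchyme-like cells made up 40.8% (39.2% to 42.4%) and 28.3% (26.8% to 29.9%), and epicardium-like cells 16.8% (15.6% to 18.0%) and 13.2% (12.0% to 14.4%). Endothelium-like cells made up 7.44% and 12.3%, mural-like cells 7.55% and 3.62%, and leukocyte-like cells 4.79% and 3.83% of S1 and S5. Smaller classes were erythroid-like (0.920% and 3.21%), neural crest-like (1.68% and 0.680%), neuron-like (1.08% and 0.618%), lymphatic-like (0.974% and 0.464%) and epithelium-like cells (0.514% and 1.67%). Unnamed clusters held 496 S1 cells (13.4%) and 590 S5 cells (18.2%), most of them cardiomyocytes. Genes linked to immune signalling were among the leading genes of some named clusters. These were Mnda and Ifi205 in an endothelium-like cluster, and the chemokine genes Cxcl13 and Ccl2 in mesenchyme-like clusters. The top 10 genes of these clusters held no leukocyte marker. The shares rest on 1 library per sample, and the filter on genes and mitochondrial UMIs, which left out 244 and 211 barcodes in S1 and 437 and 72 in S5, sets them in part. With at least 1000 genes and at most 5% mitochondrial UMIs, cardiomyocytes were 4.37% of S1 and 16.2% of S5 cells, and SAN-like cells 0.855% and 5.68%.

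**Figure D1:**
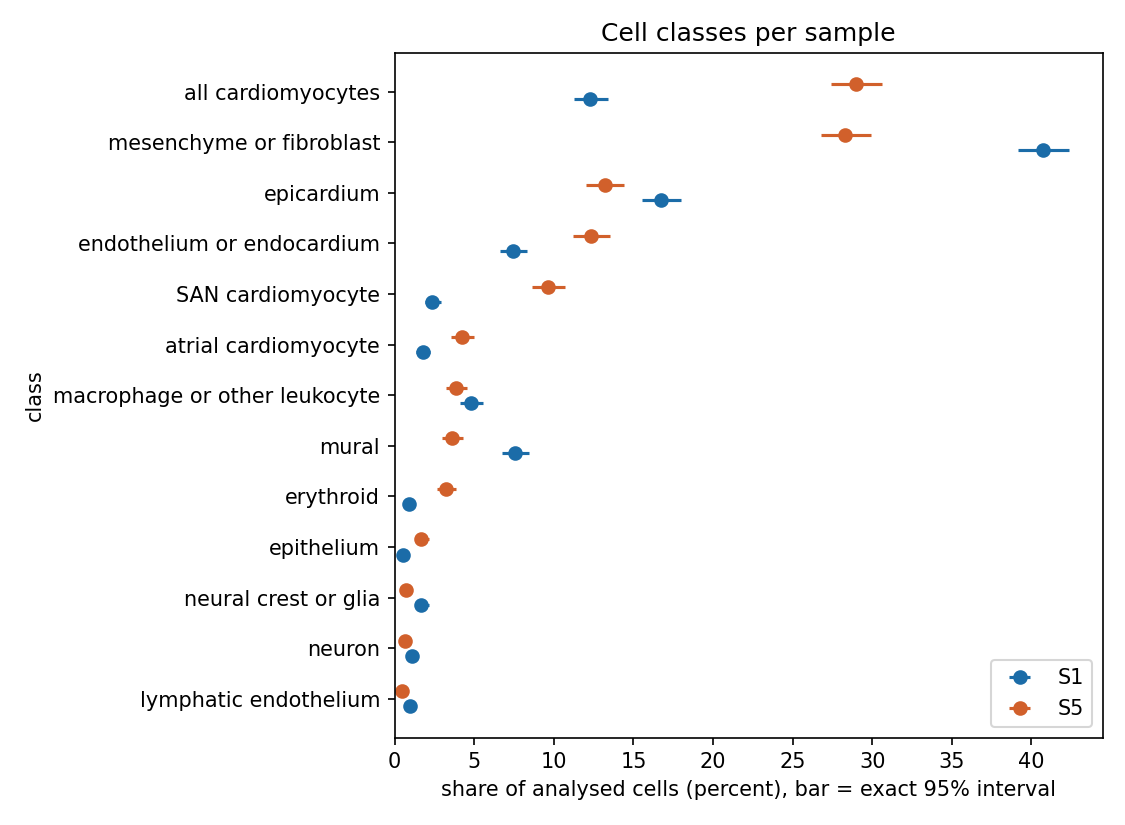
Share of analysed cells in each named class (x axis, percent of cells) for S1 (blue) and S5 deeper (orange), 1 point per sample. Bars are exact 95% intervals of counting error only. Cardiomyocytes stand at 12.3% in S1 and 29.0% in S5.

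Cardiomyocytes fell into 7 clusters that differed in Shox2, the homeobox gene that marks and maintains pacemaker cells, and in Nkx2-5, the homeobox gene of working myocardium. Clusters 1 and 4 carried Shox2, Tbx3, Tbx18, Isl1 and Hcn4, which mark the SAN, and were called SAN-like. Together they held 87 S1 cells, 2.35% of all cells (1.89% to 2.90%), and 311 S5 cells, 9.61% (8.62% to 10.7%). Cluster 3 carried Nppa, Gja5 and Nkx2-5, which mark atrial working myocardium, and was called atrial-like, with 65 S1 cells, 1.76% (1.36% to 2.24%), and 137 S5 cells, 4.23% (3.57% to 4.99%). Its top genes also held Krt19, an epicardial marker. Cluster 4 had both the SAN marker Tbx3 and the atrioventricular canal marker Bmp2 among its top 10 genes, and it entered the SAN-like class only by the last revision of the naming rule, made after the clusters had been seen. Its median depth was 10178 UMIs in S1 and 9032.5 in S5, beside 6047 and 12397 in cluster 1.

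The unnamed cardiomyocyte clusters were 302 of the S1 and 490 of the S5 cardiomyocytes (66.5% and 52.2%). Cluster 0 was led by Myl2 and Myl3, light chains of the sarcomere, and carried both Shox2 (644 and 646 CPM in S1 and S5) and Nkx2-5 (275 and 257 CPM), with Nppa at 2609 and 4048 CPM. Its 131 and 280 cells were 28.9% and 29.9% of cardiomyocytes. Cluster 2, led by the mitotic genes Ccnb1 and Cdc20, held 17.8% and 17.5%. Cluster 5, led by Plac8, Tagln and Myh11, held 6.39% and 4.48%. Its best-scoring class was SAN, with 1 marker, too few for a name, so it stands outside the SAN-like class. It carried Shox2 (375 and 240 CPM in S1 and S5) and Tbx18 (356 and 201 CPM). Nkx2-5 was low there (14.8 and 5.91 CPM), and so was Isl1 (9.88 and 5.91 CPM). Cluster 6, led by Cxcl13, Sfrp2, Dcn and Postn, held 13.4% of S1 cardiomyocytes and 0.426% of those of S5. SAN-like cells made up 19.2% and 33.2% and atrial-like cells 14.3% and 14.6% of cardiomyocytes.

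**Figure D2:**
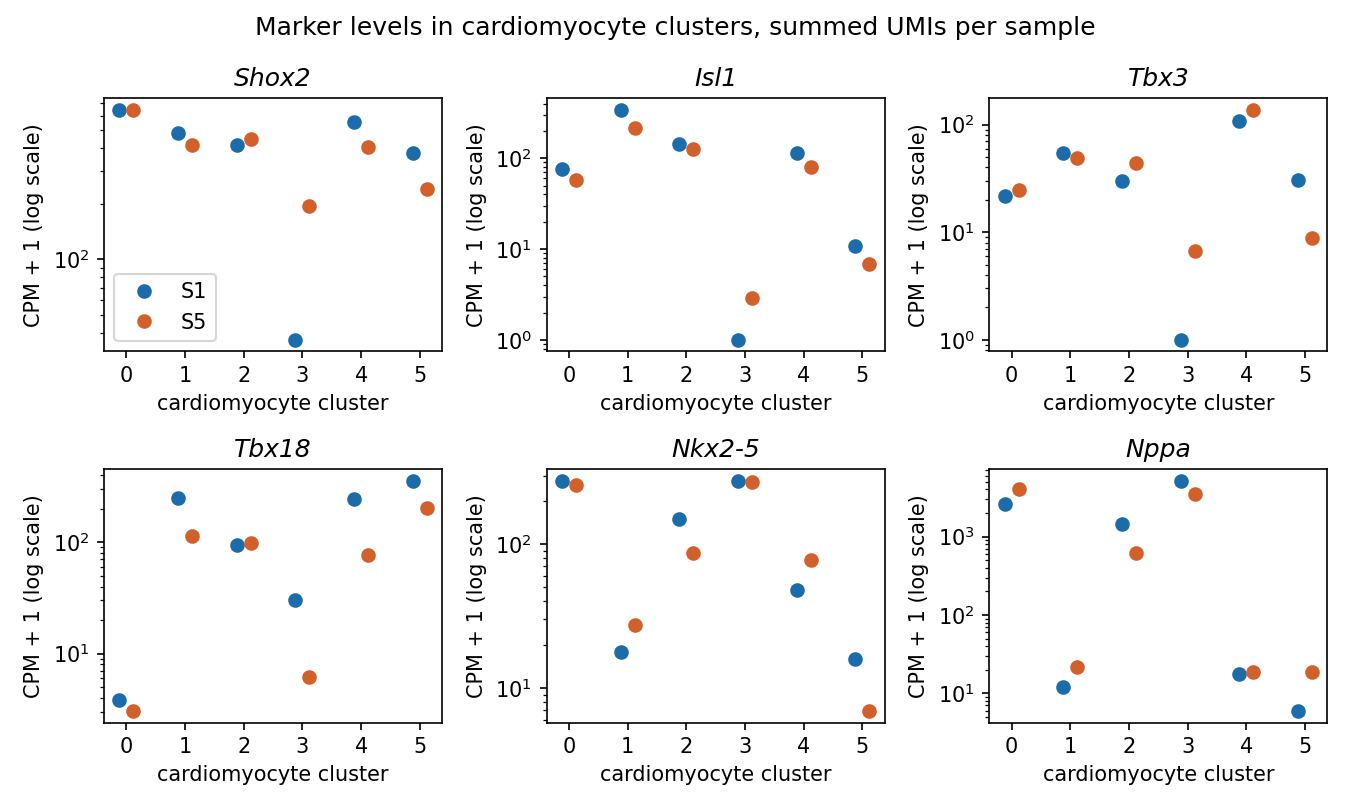
Summed level of 6 marker genes (y axes, CPM + 1, log scale) in cardiomyocyte clusters 0 to 5 (x axes), 1 point per sample, S1 blue and S5 orange. Shox2 is above 400 CPM in clusters 0, 1, 2 and 4 of both samples, while Nkx2-5 is above 250 CPM in clusters 0 and 3 of both.

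The main comparison asked which genes set SAN-like cells apart from the atrial-like cells taken with them. SAN-like cells had more mRNA for phospholamban, for G protein regulators, and for some BMP and Wnt pathway members. They had less for skeletal alpha-actin (Acta1), for the calsequestrin gene Casq1 and for connexin 43. The cardiac calsequestrin gene Casq2 did not pass. Pln, the brake on the calcium pump of the sarcoplasmic reticulum, was higher in SAN-like cells by a log2 fold change of 2.45 ± 0.32, and Casq1, a calcium-binding protein of that store, was lower at -3.01 ± 0.25, both in both samples. Acta1, skeletal alpha-actin, had the largest fall of a sarcomere gene at -5.79 ± 0.36. Bmp4, a BMP ligand, stood at 4.14 ± 0.44, and Lbh, a transcriptional cofactor of limb bud and heart, at 3.30 ± 0.24. Rgs4, which shortens signalling through Gi-coupled receptors, had 963 UMIs in SAN-like and 3 in atrial-like cells, a ratio of 131 (95% counting interval 44.7 to 636). Not all of this is particular to the SAN-like class. Cluster 0, outside both classes, also exceeded atrial-like cells for Pln (2.53 ± 0.19) and Rgs4 (509 UMIs against 3). Its Bmp4 was lower (-3.76 ± 0.27) and its Casq1 higher (2.93 ± 0.17) than in SAN-like cells.

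Of 11647 genes tested over 4215290 and 1564564 S5 UMIs and 719208 and 448341 S1 UMIs in the SAN-like and atrial-like sums, 413 were higher and 306 lower in SAN-like cells by edgeR, 719 in all, and 714 of them had the same direction in both samples. Of the 8707 genes outside the clustering features and markers, 187 were higher and 142 lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 7.61e-13 for Acta1 (log2 -5.79), 2.46e-10 for Casq1 (-3.01), 2.37e-11 for Lbh (3.30), 8.08e-08 for Bmp4 (4.14) and 2.82e-06 for Pln (2.45), each in both samples. Without the sample block, 317 genes passed, and DESeq2 gave 284 higher and 356 lower. Stricter cell filters gave 381, and the SAN-like class without cluster 4, as the earlier naming rule had it, gave 755, with 570 of the 719 calls kept.

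**Figure D3:**
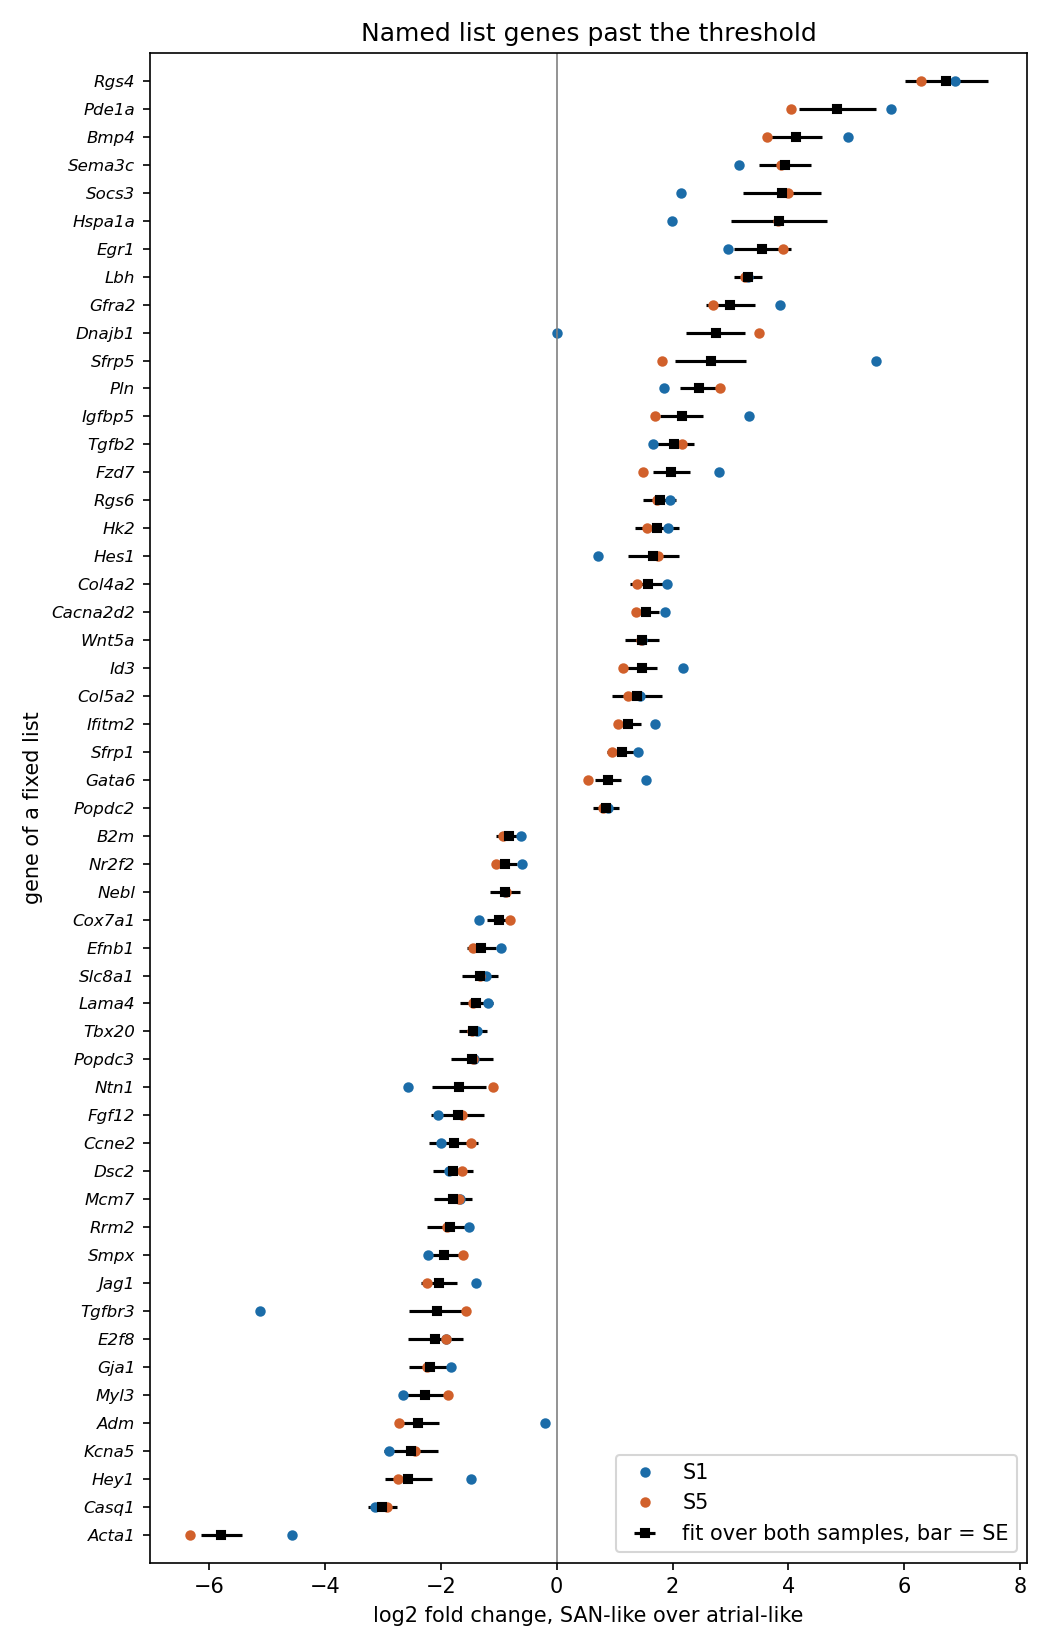
Log2 fold change of SAN-like over atrial-like cells (x axis) for the named members of the fixed lists (y axis), S1 in blue, S5 in orange and the fit over both samples in black with its SE. Acta1 (-5.79) stands lowest, and Rgs4, with 3 UMIs in atrial-like cells, highest. The Dnajb1 difference (0.01 in S1, 3.49 in S5) and that of Adm (-0.20 and -2.72) come from S5.

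The names were checked on genes that served as markers. Shox2 was higher in SAN-like cells at 1.87 ± 0.33, with 3.72 in S1 and 1.08 in S5. Tbx3 stood at 4.11 ± 0.48, Tbx18 at 3.63 ± 0.42 and Hcn4, the main pacemaker channel, at 2.92 ± 0.57. Isl1 had 901 UMIs in SAN-like and 3 in atrial-like cells, a ratio of 123 (41.8 to 595). Nkx2-5 was lower at -2.87 ± 0.28 and Nppa at -7.87 ± 0.58.

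Among ion channel and calcium genes the changes went both ways. Of 13 pacemaker and calcium current genes, 2 were higher, 1 lower and 10 did not pass, and adjusted over the list alone 2 were higher and 2 lower. Cacna2d2, an auxiliary calcium channel subunit, was higher at 1.53 ± 0.24, as was the cAMP-binding Popeye protein gene Popdc2 at 0.85 ± 0.22, while its relative Popdc3 was lower at -1.46 ± 0.37. Camera gave this list an adjusted p of 0.574. None of the 12 potassium and sodium channel genes of working myocardium was higher and 3 were lower, also adjusted over the list alone: Kcna5, an atrial repolarising channel, at -2.51 ± 0.46, Fgf12, a sodium channel modulator, at -1.71 ± 0.46, and Kcnd2, a transient outward channel named after its values were seen, which had no more than 3 UMIs in SAN-like cells. This list was lower by camera (adjusted p = 0.0169), and adjusted p = 0.304 with an estimated correlation. Of 17 calcium handling genes, Pln was higher, Casq1 and the sodium-calcium exchanger gene Slc8a1 (-1.32 ± 0.30) were lower and 14 did not pass, and adjusted over the list alone 2 were higher and 2 lower. Camera gave an adjusted p of 0.697.

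Contractile and coupling genes were lower or did not pass. Of 23 sarcomere genes, 5 were lower, 6 adjusted over the list alone, and 18 did not pass: Acta1, Myl3 (-2.27 ± 0.34), Smpx (-1.95 ± 0.25), Nebl (-0.89 ± 0.26) and, named after its values were seen, Pdlim5 (-0.68 ± 0.19). By camera the list was lower (adjusted p = 0.00130), and adjusted p = 0.640 with an estimated correlation. Of 13 gap junction and intercalated disc genes, 2 were lower: Gja1, connexin 43 of fast-conducting muscle, at -2.19 ± 0.36, and Dsc2, a desmosomal cadherin, at -1.79 ± 0.34. Adjusted over the list alone 2 were higher and 4 lower, and camera gave an adjusted p of 0.148. Cox7a1, the muscle isoform of a respiratory chain subunit, was lower at -0.99 ± 0.21, alone among 34 oxidative phosphorylation genes and 1 also when adjusted over the list alone. That list was lower by camera (adjusted p = 0.0123), and adjusted p = 0.712 with an estimated correlation.

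Metabolic genes otherwise mostly did not pass. Hk2, which commits glucose to glycolysis, was higher at 1.73 ± 0.38, the single call among 22 glycolysis genes, also adjusted over the list alone (camera adjusted p = 0.194). Cpt1a, which imports fatty acids into mitochondria and was named after its value was seen, was the single call among 19 fatty acid genes at 2.33 ± 0.66, also adjusted over the list alone. The median of that list was -0.01 and its mean 0.03, while camera's direction was down (adjusted p = 0.574).

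Whether genes of DNA replication were lower in SAN-like cells depended on the clustering and the entry used. Of 30 S phase genes, 9 were lower, 20 adjusted over the list alone, and none was higher. They included E2f8 (-2.09 ± 0.47), the ribonucleotide reductase subunit Rrm2 (-1.84 ± 0.39), the replicative helicase subunit Mcm7 (-1.79 ± 0.33) and Ccne2 (-1.78 ± 0.42). The list was lower by camera (adjusted p = 1.56e-11), and adjusted p = 0.304 with an estimated correlation. With fry, which asks whether a list's genes move on balance in 1 direction, the adjusted p was 0.0226. With S5 first in place of S5 deeper, which also changed the clustering, 0 of the 30 genes passed, also adjusted over the list alone. The median of the list was then 0.05 and its adjusted p 0.787 by camera and 0.997 by fry, with Rrm2 at 0.51 and Ccne2 at 0.04. With S5 deeper, Rrm2 stood at 0.36 at resolution 1, and at 1.68 with own-marker names there. Without the sample block 4 S phase genes were lower. Of 35 G2 and M phase genes edgeR called 0, also adjusted over the list alone, although camera called the list lower (adjusted p = 0.0251), and adjusted p = 0.764 with an estimated correlation. With S5 first that list's direction was up, at a camera adjusted p of 0.311 in a range of 1.68e-05 to 0.512 over the alternatives. Cluster 2, led by mitotic genes, stands outside both classes. Single cells were not assigned a phase, so cells in mitosis may remain in both classes.

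Transcription factor and signalling genes were mostly higher where they passed. Of 31 cardiac and SAN transcription factor genes, 4 were higher and 2 lower, also adjusted over the list alone. Lbh and Gata6 (0.88 ± 0.23) were among the higher, and Tbx20, a T-box factor of chamber muscle, at -1.44 ± 0.24 and Nr2f2, which sets atrial identity, at -0.89 ± 0.20 were the lower. Of 24 BMP and TGF-beta genes, 4 were higher and 1 lower, also adjusted over the list alone. Bmp4, the ligand Tgfb2 (2.02 ± 0.34) and the BMP target Id3 (1.47 ± 0.27) were higher, and the co-receptor Tgfbr3 was lower at -2.07 ± 0.47. Of 22 Wnt genes, 4 were higher, also adjusted over the list alone. These were the secreted Wnt antagonists Sfrp5 (2.66 ± 0.61) and Sfrp1 (1.13 ± 0.26), the receptor Fzd7 (1.98 ± 0.32) and the ligand Wnt5a (1.48 ± 0.29). By camera the first 2 lists were higher (adjusted p = 0.0169 each) and so was the Wnt list (adjusted p = 0.0225), and adjusted p = 0.304 with an estimated correlation for each of these.

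Notch genes split: the ligand gene Jag1 (-2.03 ± 0.31) and the target gene Hey1 (-2.56 ± 0.41) were lower and Hes1, another target, was higher (1.67 ± 0.44), of 13 tested, with the same counts adjusted over the list alone. The median of the Notch list was 0.30, or 0.58 with low-count genes at their bound, its mean -0.05, and camera's direction down (adjusted p = 0.729). Crabp1, a retinoic acid binding protein named after its value was seen, was the single call among 11 retinoic acid genes at 1.83 ± 0.54, also adjusted over the list alone (camera adjusted p = 0.679).

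Genes of autonomic signalling included Rgs4, Pde1a, a cyclic nucleotide phosphodiesterase with 221 UMIs in SAN-like and 3 in atrial-like cells (ratio 30.1, 10.1 to 147), and Rgs6 at 1.78 ± 0.29. Of 24 such genes, 3 were higher and 1, Prkar2b (-1.85 ± 0.56, named after its value was seen), was lower; adjusted over the list alone 4 were higher and 1 lower. The list was higher by camera (adjusted p = 0.0225), and adjusted p = 0.304 with an estimated correlation. Of 29 neuronal and axon guidance genes, 4 were higher and 4 lower, also adjusted over the list alone. Sema3c, a secreted guidance cue, stood at 3.94 ± 0.45 and Gfra2, the neurturin receptor, at 3.0 ± 0.42, while Ntn1 (-1.68 ± 0.47) and Efnb1 (-1.30 ± 0.25) were lower. The median of this list was 0.07, or -0.06 with low-count genes at their bound, its mean 0.57, and camera's direction up (adjusted p = 0.729).

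Among matrix and stress genes more passed as higher than as lower. Of 34 extracellular matrix genes, 7 were higher, 1 was lower and 26 did not pass, and adjusted over the list alone 9 were higher and 3 lower. Igfbp5 (2.15 ± 0.37) and the collagen genes Col4a2 (1.57 ± 0.31) and Col5a2 (1.39 ± 0.43) were higher and the laminin gene Lama4 (-1.39 ± 0.28) lower. By camera the list was higher (adjusted p = 0.0499), and adjusted p = 0.712 with an estimated correlation. With cluster 1 alone as the SAN-like class 6 matrix genes were higher and 3 lower. Col3a1, a mesenchymal marker outside this list, was also higher in SAN-like cells at 1.84 ± 0.45. Of 22 dissociation stress genes, which respond within minutes to handling of tissue, 11 were higher and 11 did not pass; adjusted over the list alone 14 were higher and 1 lower, and without the sample block 3 were higher. Socs3 stood at 3.89 ± 0.67, Hspa1a at 3.83 ± 0.83, Egr1 at 3.55 ± 0.49 and Dnajb1 at 2.75 ± 0.51. For Dnajb1 the S1 library gave 0.01 and S5 gave 3.49, and the split of reads between Hspa1a and its near-identical copy Hspa1b is uncertain. In S1, SAN-like and atrial-like cells held 2 and 0 UMIs of Hspa1a and 10 and 1 of Socs3. The sizes of these differences therefore rest mostly on S5, while Egr1 stood at 2.95 in S1 and 3.90 in S5. Camera called the list higher (adjusted p = 0.000292), and adjusted p = 0.501 with an estimated correlation.

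Of 14 hypoxia genes, Adm, a vasodilator peptide gene, was lower at -2.39 ± 0.36 (-0.20 in S1 and -2.72 in S5) and Egln3, named after its value was seen and near the floor in atrial-like cells, was higher. Adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.729). Of 10 interferon and antigen presentation genes, Ifitm2 was higher at 1.24 ± 0.22 and B2m lower at -0.82 ± 0.22, the same counts as adjusted over the list alone. The median of that list was 0.25, or -0.02 with low-count genes at their bound, its mean 0.83, and camera's direction up (adjusted p = 0.966). In all, camera called 11 of the 21 lists with the preset correlation and 0 with the estimated correlation. Fry called 7: S phase, the potassium and sodium channels, gap junction, transcription factor, BMP and TGF-beta, Wnt and autonomic lists, the last 6 at an adjusted p of 0.0144 each. With the earlier SAN-like class camera called 4 lists, and with S5 first 7, of which 6 are among the 11.

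Outside the lists, markers and clustering features, the largest rise was that of Cachd1, with 133 UMIs in SAN-like and 0 in atrial-like cells, at least 18.1-fold higher. It was followed by Mfsd6 (2.87 ± 0.47), the endoplasmic reticulum transcription factor gene Creb3l1 (2.81 ± 0.55), Tiparp (2.64 ± 0.44) and the adhesion gene Sdk2 (2.49 ± 0.43). Lclat1, Lrrn2, Kctd1, Dpy19l1 and Prps2 stood between 1.91 and 2.24. The largest falls were those of the calcium-binding protein gene Gca (-2.19 ± 0.44), Dbt of branched-chain amino acid breakdown (-2.17 ± 0.42), Lama5 (-1.88 ± 0.38), Comtd1 (-1.82 ± 0.38) and the phosphodiesterase gene Pde3b (-1.82 ± 0.41). Pde4dip, Ror2, Cast, Ppat and Glrb completed the lower genes.

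On GRCm38, Shox2 (ENSMUSG00000027833) lies on chromosome 3 from 66971727 to 66981771 and Nkx2-5 (ENSMUSG00000015579) on chromosome 17 from 26838664 to 26845009. Pln (ENSMUSG00000038583) lies on chromosome 10 from 53337667 to 53345987, Casq1 (ENSMUSG00000007122) on chromosome 1 from 172209894 to 172219868 and Acta1 (ENSMUSG00000031972) on chromosome 8 from 123891769 to 123894751. Gja1 (ENSMUSG00000050953) lies on chromosome 10 from 56377330 to 56402513 and Cacna2d2 (ENSMUSG00000010066) on chromosome 9 from 107399612 to 107529343. Bmp4 (ENSMUSG00000021835) lies on chromosome 14 from 46383520 to 46390669, Lbh (ENSMUSG00000024063) on chromosome 17 from 72918305 to 72941947 and Hey1 (ENSMUSG00000040289) on chromosome 3 from 8663359 to 8667256. Rgs4 (ENSMUSG00000038530) lies on chromosome 1 from 169741477 to 169747642, Pde1a (ENSMUSG00000059173) on chromosome 2 from 79834453 to 80129458 and Sema3c (ENSMUSG00000028780) on chromosome 5 from 17574281 to 17730268. Gfra2 (ENSMUSG00000022103) lies on chromosome 14 from 70890120 to 70979838 and Vcan (ENSMUSG00000021614) on chromosome 13 from 89655312 to 89742509. All are annotated as protein coding.

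The share of cycling cells depended on the number of UMIs asked for. After thinning to 4956 UMIs, 78.5% of SAN-like S1 cells (51 of 65, exact 95% interval 66.5% to 87.7%) and 59.8% of SAN-like S5 cells (180 of 301, 54.0% to 65.4%) held at least 3 UMIs of cell cycle genes. Of atrial-like cells, 75.0% in S1 (42 of 56, 61.6% to 85.6%) and 70.4% in S5 (95 of 135, 61.9% to 77.9%) did. With at least 5 UMIs the S5 shares were 29.9% (24.8% to 35.4%) of SAN-like and 45.2% (36.6% to 54.0%) of atrial-like cells, and those of S1 53.8% (41.0% to 66.3%) and 58.9% (45.0% to 71.9%). No test was made of these differences. Thinning left out 22 and 10 SAN-like and 9 and 2 atrial-like cells. Unthinned, the shares were 73.6% and 86.2% for SAN-like and 80% and 92.0% for atrial-like cells. All 71 S1 and 160 S5 cells of the mitotic cluster 2 passed, and they stand outside both classes. Cluster 2 carried Shox2, Isl1 and Tbx18 beside Nppa and Nkx2-5, so the shares of both classes leave out dividing cells with markers of each. In cluster 0 the shares were 66.7% and 50.4%, and among all cardiomyocytes gated by UMIs they were 83.6% and 68.4% with Shox2 alone, 85% and 67.1% with Nkx2-5 alone and 70.4% and 61.4% with both.

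Shox2 and Nkx2-5 were found in the same cells of some cardiomyocyte clusters. After thinning to 5420 UMIs, Nkx2-5 was detected in 13.1% of SAN-like S1 cells and 17.8% of SAN-like S5 cells (23.0% and 30.5% unthinned), beside 61.1% and 75.2% of atrial-like cells (76.9% and 94.9% unthinned). Mesenchyme-like cells, which should lack Nkx2-5, gave 1.18% and 0.677%. Shox2 was detected in 91.8% and 84.8% of SAN-like cells and in 13.0% and 50.4% of atrial-like cells, beside 3.70% and 7.98% of mesenchyme-like and 1.33% and 2.41% of endothelium-like cells. Median depths before thinning were 6713 and 11659 UMIs in SAN-like, 6663 and 10838 in atrial-like, 4606.5 and 7583.5 in mesenchyme-like and 6391 and 8569 in endothelium-like cells. Both genes were detected together in 26.1% of S1 cardiomyocytes (84 of 322, 21.4% to 31.2%) and 33.0% of S5 cardiomyocytes (294 of 892, 29.9% to 36.2%). In cluster 0 they were together in 69.4% (43 of 62) and 64.7% (167 of 258), in SAN-like cells in 13.1% and 15.8% and in atrial-like cells in 11.1% and 36.1%.

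Part of the Shox2-positive cells of the node also carries Nkx2-5. Within the SAN-like class, cells with Nkx2-5 detected after thinning were therefore compared with cells in which it was not detected. Full counts were then summed, so the undetected state also holds S5 cells with Nkx2-5 UMIs. Unthinned, Nkx2-5 was detected in 23.0% of SAN-like S1 and 30.5% of SAN-like S5 cells. The contrast is thus one of detection, not of presence against absence. Cells with Nkx2-5 detected had more mRNA for the nuclear receptors Nr2f2 (1.49 ± 0.22) and Nr2f1 (1.03 ± 0.13) and for the matrix genes Vcan (1.60 ± 0.23) and Fbln1 (1.43 ± 0.23). They also had more for Ppargc1a, a coactivator of mitochondrial genes (1.11 ± 0.24). They had less of Rgs4 (-1.43 ± 0.21), of the neurturin receptor gene Gfra2 (-1.27 ± 0.34), of the Wnt antagonist gene Sfrp1 (-0.85 ± 0.12) and of the fatty acid binding protein gene Fabp3 (-0.74 ± 0.12). All of these had the same direction in both samples, as the rule for named genes requires. The states differ in their mix of clusters 1 and 4, so their difference is not separate from that between the clusters. Cells with Nkx2-5 detected were 5 of 6 from cluster 4 in S1 and 26 of 45 in S5. Of the undetected cells, 22 of 55 and 76 of 252 were. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 78 genes were higher and 114 lower of 6045 tested, 176 of them in the same direction in both samples, and 29 and 37 of 4935 outside the clustering features. The adjusted p of Nr2f2 was 6.67e-09 at a log2 fold change of 1.49.

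By group, 3 of 23 transcription factor genes were higher (5 adjusted over the list alone), Nr2f2, Nr2f1 and Prdm6 (1.15 ± 0.32). Of 21 sarcomere genes, Csrp3 (0.55 ± 0.09), Mybpc3 (0.48) and Ankrd1 (0.41) were higher and Des (-0.56) lower, with 3 and 3 adjusted over the list alone. Of 34 oxidative phosphorylation genes, Cox7a1 (0.58) and Cox6a2 (0.43) were higher. Of 19 glycolysis genes, 4 were lower, 7 adjusted over the list alone, with Ldha at -0.50, Pgam1 at -0.46 and Eno3 at -0.45. Of 12 BMP and TGF-beta genes, Id2 (0.92 ± 0.14) and Bambi (0.77 ± 0.19) were higher. Cpne5 (1.38 ± 0.22) and the ephrin receptor gene Epha4 (1.0 ± 0.24) were the 2 higher and 1 was lower of 11 neuronal and guidance genes, and of 20 matrix genes 2 were higher and 3 lower, Sparc (-0.69 ± 0.11) and Igf1 (-0.98) among these. Bves, a Popeye protein gene, was higher at 0.94 ± 0.24, and Hes1 (-1.10), Fxyd1 (-0.49) and Mif (-0.48) were lower. Stress genes moved with this state: 5 of 22 were higher, 8 adjusted over the list alone, with Klf6 at 1.04, Atf3 at 0.93, Ier5 at 0.92 and Jun at 0.87.

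Outside the lists, Aqp4, a water channel gene, was higher at 2.16 ± 0.65, with Gpatch8, Rab2a and Sptbn1. The lower genes were Uso1 (-1.24), Rcn1 (-0.76), Ssr2 (-0.76), P4hb (-0.73), Erp29 (-0.71), Tmed10 (-0.64) and Dad1 (-0.64), beside Lrrn2 (-0.99), Gpx8 (-0.82) and Maged1 (-0.76). Haemoglobin UMIs differed between the states too: Hba-a1 stood at -2.12 ± 0.12, from -0.48 in S1 and -2.18 in S5. Shox2 stood at 0.09 ± 0.12 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.858), Tbx3 at 0.36, Hcn4 at 0.13, Isl1 at -0.57 and Tbx18 at -1.51 ± 0.27. The Nkx2-5-detected state held 6 S1 cells and 59415 UMIs, so the S1 values rest on few counts. The comparison is not settled: DESeq2 called 6 genes, edgeR without the sample block 0 (245 at an unadjusted p under 0.05), the fit on thinned counts 39, S5 first 81, and cluster 1 alone as the SAN-like class 0 (30 at an unadjusted p under 0.05, with 1 detected S1 cell). In cluster 1 alone Nr2f1 (-0.15), Csrp3 (-0.47), Epha4 (-0.52) and Sfrp1 (0.04) were among the genes that changed sign.

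The series title asks about heterogeneity of SAN cells, and the SAN-like class held clusters 1 and 4. With S5 first the matching cluster 4 (45 S1 and 115 S5 cells) was named atrioventricular canal by its own markers, so this comparison may set the SAN against another tissue. Cluster 4 had more mRNA for Vcan (2.83 ± 0.25), a matrix proteoglycan, for Lbh (2.54 ± 0.17), Prdm6 (2.1 ± 0.35) and Bmp4 (1.52 ± 0.18), and for Ppargc1a (1.87 ± 0.20). Cluster 1 had more for Gfra2 (-3.28 ± 0.32 for cluster 4 over cluster 1), Rgs4 (-2.87 ± 0.20), Smpx (-2.79 ± 0.17), the guidance cue gene Sema3c (-2.48 ± 0.28) and Casq2, the cardiac calsequestrin gene (-2.18 ± 0.23). Gja1 had 73 UMIs in cluster 1 and 3 in cluster 4, a ratio of 12.3 (4.05 to 61.1). All had the same direction in both samples, which the rule for named genes requires. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 278 genes were higher and 364 lower in cluster 4 of 7355 tested, 631 of the 642 in the same direction in both samples, and 121 and 180 of 5945 outside the clustering features. The adjusted p of Lbh was 2.29e-08 at a log2 fold change of 2.54. Lbh, Bmp4 and Rgs4 are list genes, kept out of clustering, that also lead these clusters. Both clusters were cut by expression from the same cells that were tested, so a difference was built in, also for genes correlated with the features. The p-values therefore do not test whether the clusters are separate kinds of cell. Clustering and testing on separate parts of the UMIs was not run for this comparison.

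Of 26 transcription factor genes, 8 were higher and 3 lower in cluster 4, or 9 and 4 adjusted over the list alone, with Sox5 at 1.95 ± 0.38 and Nr2f1 at 1.72 ± 0.14. Of 13 BMP and TGF-beta genes, 4 were higher, 5 adjusted over the list alone, Id4 (1.56) and Id2 (0.92) among them, and of 12 Wnt genes 3 were higher, the receptor genes Fzd7 (1.21 ± 0.20) and Fzd1 (1.06) and Tcf7l2 (0.77), and Sfrp1 was lower (-1.08). Of 11 pacemaker and calcium current genes, 4 were higher and 1 lower, with the pacemaker calcium channel gene Cacna1d at 1.12 ± 0.27, Bves at 0.72, Popdc2 at 0.68 and Kcnj5 at 0.64. The potassium channel gene Kcnk3 was lower at -1.95 ± 0.25. Of 15 calcium handling genes, 2 were higher, Sln (0.93) among them, and 3 lower, Casq2, Pln (-0.91) and Hrc (-0.81). Of 22 sarcomere genes, 2 were higher and 6 lower, with Ankrd1 at 1.45 ± 0.11 and Des at -0.94. The nodal connexin gene Gjc1 was higher at 0.92 and the desmosomal gene Dsp lower at -1.17 ± 0.20.

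Of 34 oxidative phosphorylation genes, 1 was higher (Cox7a1, 0.77) and 6 lower, 9 adjusted over the list alone, with Cox8b at -2.42 ± 0.21. Of 22 glycolysis genes, the glucose transporter gene Slc2a3 was higher at 3.20 ± 0.49 and 6 were lower, 10 adjusted over the list alone, with Eno3 at -0.89 and Ldha at -0.73. The fatty acid genes Fabp3 (-0.98) and Lpl (-0.82) were lower. Pde1a was higher at 1.81 ± 0.25. Of 24 matrix genes, 8 were higher and 2 lower, with Fbln1 at 1.43, Ctgf at 1.13 and Cyr61 at 1.04. Of 11 neuronal and guidance genes 4 were higher and 3 lower, Cpne5 (1.20) and Epha4 (1.09) among the higher. Stress genes moved with cluster 4 here too: 4 of 22 were higher and 1 lower, with Ier3 at 0.91, Klf6 at 0.89, Ier5 at 0.81 and Jun at 0.63. Of 14 G2 and M phase genes, 1 was higher and 0 lower, or 9 and 0 adjusted over the list alone. Of 21 S phase genes 0 passed, also adjusted over the list alone. Outside the lists, Rnd2 (3.65 ± 0.54), Unc13c (3.64 ± 0.45), Aqp4 (3.41 ± 0.54), Ctnnal1 (2.94) and the glutamate receptor gene Gria1 (2.90 ± 0.37) were higher, and Creb3l1 (-2.25), Tenm2 (-2.25) and Rbfox1 (-2.11) lower.

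Shox2 did not differ between the clusters (-0.06; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.821), while Tbx3 (1.30 ± 0.19) and Nkx2-5 (1.41 ± 0.24) were higher and Isl1 lower (-1.64 ± 0.16) in cluster 4. Hcn4 stood at 0.74 and Tbx18 at -0.46, neither past the threshold. DESeq2 gave 41 higher and 84 lower genes and edgeR without the sample block 80. This comparison exists only under the last revision of the naming rule.

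Each named class was also set against the mean of the others for the 452 list genes tested. In SAN-like cells 230 were higher and 114 lower, with all 17 calcium handling and all 34 oxidative phosphorylation genes, 11 of 13 pacemaker genes and 15 of 24 autonomic genes among the higher. Pln stood at 6.52 ± 0.24, the G protein-gated channel gene Kcnj5 at 5.96 ± 0.28, Rgs6 at 5.57 ± 0.25 and the adenosine receptor gene Adora1 at 5.05. Of 35 G2 and M phase genes, 30 were lower in SAN-like and 30 in atrial-like cells, both of which leave out the mitotic cardiomyocytes of cluster 2, so this is no result on their cycling. In atrial-like cells 203 were higher and 119 lower, with all 23 sarcomere, all 34 oxidative phosphorylation, 15 of 17 calcium handling and the same number, 11 of 13, of pacemaker genes higher, so this contrast mostly sets cardiomyocytes apart from the other classes. Of 22 stress genes, 9 were higher and 7 lower in SAN-like cells, and 0 higher and 15 lower in atrial-like cells. Acta1 stood at 6.58 ± 0.22 and Casq1 at 5.61.

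Endothelium-like cells had 109 list genes higher and 134 lower. The transcription factor gene Irx5 stood at 6.95 ± 0.36, Mfng, a glycosyltransferase acting on Notch, at 5.97 ± 0.29, the matrix link protein gene Hapln1 at 5.86 ± 0.21 and Notch1 at 3.25. Of 13 Notch genes 7 were higher, of 10 interferon and antigen presentation genes 8, and of 35 G2 and M phase genes 17. Epicardium-like cells had 124 higher and 86 lower, with 15 of 22 Wnt, 12 of 24 BMP and TGF-beta and 20 of 34 matrix genes higher. Rspo1, an enhancer of Wnt signalling, stood at 6.38 ± 0.22, Sema3d at 3.85, Sfrp2 at 2.92 and Wnt5b at 2.44.

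Mesenchyme-like cells had 153 higher and 89 lower. There, 27 of 34 matrix genes, 19 of 24 BMP and TGF-beta genes, 24 of 29 neuronal and guidance genes and 9 of 11 retinoic acid genes were higher, and so were 12 of 22 stress genes, with Crabp1 at 4.32 ± 0.14, Sfrp2 at 3.72 ± 0.19, Col6a3 at 3.62 ± 0.21 and the activin subunit gene Inhba at 3.40. Mural-like cells had 118 higher and 58 lower, with 8 of 13 Notch genes and 20 of 34 matrix genes higher, among them the Notch targets Nrarp (6.40 ± 0.28) and Heyl (5.80 ± 0.23), the ligand gene Jag1 (3.79) and the elastin gene Eln (6.06 ± 0.23).

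Leukocyte-like cells had 85 higher and 115 lower, with 9 of 10 interferon and antigen presentation genes and 16 of 22 stress genes higher. Psmb8 of the immunoproteasome stood at 10.07 ± 0.37 and Irf7 at 8.07 ± 0.55. Neuron-like cells had 38 higher and 84 lower, with the neurofilament genes Nefm at 9.21 ± 0.23 and Nefl at 9.04 ± 0.19 and the synaptic gene Snap25 at 7.78 ± 0.61. Neural crest-like cells had 37 higher and 16 lower, with Gfra1 at 4.46 ± 0.48 and Sema3c at 3.62 ± 0.35. The erythroid-like sums held cardiomyocyte genes: 58 list genes were higher and 3 lower, 15 of 23 sarcomere genes among the higher, with Myl3 at 3.40 ± 0.61 and Tcap at 3.09 ± 0.54.

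The S5 entries shared 3754 barcodes, while S1 shared 23 with each of them. Deeper sequencing gave a median of 1.68 times the UMIs and 1.39 times the genes per shared barcode. Of 3147 cells kept in both, 2804 (89.1%) had the same name by own markers, and of 930 shared cardiomyocytes 743 (79.9%) did. S1 and S5 were compared within each class with no test, at 1 library each. In SAN-like cells 71 of 5976 genes at 20 CPM or more were at least 2-fold higher in S1 and 259 in S5, and log2 CPM correlated across genes at 0.940. In atrial-like cells 148 and 328 of 5664 genes differed so, at 0.927. Over the classes this correlation ran from 0.739 in neural crest-like to 0.961 in endothelium-like cells; it is across genes, which are not independent replicates.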

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

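No explanation was tested in this part, and the values below were picked out after clustering as signals in cells and barcodes that the comparisons left out. Among barcodes left out for having under 500 genes, haemoglobin genes made up 89.2% of UMIs in S1, where all 244 such barcodes were mostly haemoglobin. In S5 deeper they made up 93.1%, over 437 such barcodes. An unnamed cluster of 229 cells, 143 from S1 and 86 from S5, was led by the cartilage matrix genes Col9a3, Matn4 and Col9a1, with Col2a1 and Sox9 also among its top genes. A cluster of 36 cells, 32 from S1 and 4 from S5, was led by Myog and Mylpf, genes of skeletal muscle, with Myod1 among its top genes. A cluster of 29 cells, 19 from S1 and 10 from S5, was led by the smooth muscle genes Myh11, Mylk and Actg2.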

How the results depend on the processing

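Cluster 1 alone, own-marker names, removal of the highest doublet scores, unnamed classes in the fit, cycling by UMI gates and every comparison of cluster 0 and of cells with both UMIs were chosen after the results were seen. Over all comparisons, 2729 of 3575 values of named genes under alternatives with a test kept their direction and their side of the threshold, 811 kept the direction but no longer passed, 4 newly passed and 31 reversed; 17 had no adjusted p from DESeq2 and were left out. No named gene reversed under DESeq2 or under its size factors in edgeR. SAN-like against atrial-like cells gave 719 genes, and between 487 and 1004 under 19 of its 21 alternatives other than leaving out a sample; the exceptions follow.

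No model could be tested with 1 sample left, so leaving out a sample shows only how many called genes keep their direction: 714 to 719 for SAN-like against atrial-like cells, 176 to 192 for Nkx2-5 states, 631 to 642 for cluster 4 against 1, 1288 to 1299 for cluster 0 against SAN-like, 488 to 494 for cluster 0 against atrial-like cells, and 324 for cells with both UMIs. With 1 sample left, 888 of 894 values of named genes kept their direction. This was fixed in advance for all but the name checks, since the other genes were named only with the same direction in both samples. The 6 values that reversed were all name checks. Signs split by sample for Shox2 (-0.076 to 0.131) and Tbx3 (-0.18 to 0.42) between Nkx2-5 states, for Shox2 (-0.16 to 0.079) and Nppa (-0.31 to 0.40) between clusters 4 and 1, and for Nppa (-0.98 to 0.24) and Nkx2-5 (-0.050 to 0.017) between cluster 0 and atrial-like cells.

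Without the sample block the counts were 317 for SAN-like against atrial-like cells, 0 for Nkx2-5 states (245 at an unadjusted p under 0.05), 80 for cluster 4 against 1, 380 and 71 for cluster 0 against SAN-like and atrial-like cells, and 0 for cells with both UMIs (466 at an unadjusted p under 0.05). Within lists, removing the block moved stress genes called higher from 11 to 3, S phase genes called lower from 9 to 4, matrix genes called higher from 7 to 3, transcription factor genes called higher from 4 to 1 and sarcomere genes called lower from 5 to 3. DESeq2 called 6 genes for Nkx2-5 states, 125 for cluster 4 against 1, 491 and 201 for cluster 0, and 71 for cells with both UMIs. Stricter cell filters gave 381 genes for SAN-like against atrial-like cells. Nkx2-5 states gave 81 genes with S5 first, 39 on thinned counts and 0 (30 at an unadjusted p under 0.05, DESeq2 not run there) with cluster 1 alone. The cause was not tested, except that thinning and cluster 1 alone leave fewer UMIs and cells.

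Camera called 11 lists, and 7 with S5 first (6 of the 11, and fatty acid metabolism), 6 with clustering and testing on separate parts of the UMIs, 4 with cluster 1 alone and 0 with an estimated correlation. Lists whose direction reversed were outside the threshold in that setting: interferon at an adjusted p of 0.915 without the block (range over its alternatives 0.797 to 0.966), hypoxia at 0.848 with 2 classes and 0.944 with S5 first (0.528 to 0.944), G2 and M at 0.311 with S5 first (1.68e-05 to 0.512), Notch at 0.891 with separate parts of the UMIs, and pacemaker channels at 0.972 with cluster 1 alone (both 0.495 to 0.972). The cause was not tested.

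Stricter cell filters changed the shares in S1 to 0.855% SAN-like, 0.723% atrial-like, 6.54% endothelium-like, 18.7% epicardium-like, 0.493% erythroid-like, 38.2% mesenchyme-like, 8.62% mural-like and 4.37% cardiomyocytes. In S5 they gave 5.68% SAN-like, 2.08% atrial-like, 14.4% endothelium-like, 16.1% epicardium-like, 1.12% erythroid-like, 30.5% mesenchyme-like and 16.2% cardiomyocytes. With S5 first, mesenchyme-like cells were 33.1% of S1 and 24.6% of S5, and erythroid-like cells 1.39% of S5. With doublet calls kept, mesenchyme-like cells were 35.6% and 26.2%. The cause was not tested.

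Cycling shares moved with the number of UMIs asked for. With at least 2 they were 89.2% and 79.1% in SAN-like and 89.3% and 83.0% in atrial-like cells of S1 and S5, and with at least 5 they were 53.8% and 29.9%, and 58.9% and 45.2%. With S5 first, thinned to fewer UMIs, they were 63.9% and 47.5%, and 53.3% and 46.3%. With all UMIs the S5 shares were 86.2% and 92.0%. The gate on Shox2 without Nkx2-5 gave 68.4% in S5.

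Genes that reversed between SAN-like and atrial-like cells were Rrm2 (0.51) and Ccne2 (0.036) with S5 first, Rrm2 (0.36) at resolution 1, Ntn1 (0.00042) by gates, and by own-marker names Rrm2 (0.17), Ccne2 (0.10) and Shox2 (-0.17) at resolution 0.25, Rrm2 (1.68) at resolution 1, and E2f8 (0.035), Rrm2 (0.15) and Ccne2 (0.18) with strict filters. Between Nkx2-5 states, cluster 1 alone reversed Bves (-0.14), Fxyd1 (0.074), Csrp3 (-0.47), Ankrd1 (-0.26), Cox6a2 (-0.50), Ldha (0.38), Nr2f1 (-0.15), Id2 (-0.34), Sfrp1 (0.044), Epha4 (-0.52), Mif (0.27), Sptbn1 (-0.32), Shox2 (-0.074) and Tbx3 (-0.17). S5 first reversed Ier5 (-0.40), Tbx3 (-0.22) and Hcn4 (-0.31), and no filter on counts reversed Shox2 (-0.031). Between clusters 4 and 1, S5 first reversed Shox2 (0.086), and between cluster 0 and atrial-like cells no filter reversed Nkx2-5 (0.0058). The cause was not tested.

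No value could be had at resolution 0.25 with transferred names, where the atrial-like cluster and cluster 0 form 1 cluster, with own-marker names after removal of the highest doublet scores, where no class had the atrial name, or for a gate of at least 2 Nkx2-5 UMIs. In simulated counts the SAN-like against atrial-like test recovered 3.09% of 2-fold changes, so its uncalled genes are not shown to be unchanged.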

Other observations

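The comparisons of cardiomyocyte cluster 0 and of cells with UMIs of both genes, and the depth tests of clusters 6 and 0, were chosen after the clusters were seen. Cluster 0 was cut by expression from the same cells that were tested, so its p-values do not test whether it is a separate kind of cell. Cluster 0 carried Shox2 beside Nkx2-5 and Nppa. Its best-scoring class was ventricular, with 1 marker, too few for a name. Against SAN-like cells it had more mRNA for Acta1 (3.96 ± 0.35), Myl3 (3.39 ± 0.22), Casq1 (2.93 ± 0.17), the atrial repolarising channel gene Kcna5 (2.67 ± 0.35) and the sodium channel family gene Scn7a (2.69 ± 0.40). It had more for the guidance cue gene Sema3a (2.43 ± 0.24), Hey1 (2.17), Jag1 (1.72) and Nr2f2 (1.58 ± 0.15). It had less for Pde1a (-3.81 ± 0.37), Bmp4 (-3.76 ± 0.27), Sema3c (-3.48 ± 0.32), Nrp1 (-2.84), Hes1 (-2.75), Tgfb2 (-2.59), Sfrp1 (-2.44 ± 0.16) and Lbh (-1.73). Shox2 stood at 0.58, not past the threshold, with Nppa at 7.52, Nkx2-5 at 2.77 and Tbx18 at -5.80. Of 34 oxidative phosphorylation genes 23 were higher and of 22 sarcomere genes 15, while 15 of 27 matrix genes and 10 of 21 stress genes were lower. By edgeR's quasi-likelihood test, at a Benjamini-Hochberg adjusted p under 0.05, 611 of 7984 genes were higher and 688 lower, 1288 of these 1299 in the same direction in both samples; DESeq2 called 491 and edgeR without the sample block 380.

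Against atrial-like cells, cluster 0 had more mRNA for Pln (2.53 ± 0.19), Sema3a (2.40 ± 0.30), the synaptotagmin gene Syt1 (2.28), Vcan (2.12 ± 0.20) and Cox8b (1.39), and for Rgs4, with 509 UMIs against 3 (ratio 93.4, 95% counting interval 31.8 to 454). It had less for Cdc45 (-3.49), Gja1 (-3.24 ± 0.34), Tbx20 (-2.40 ± 0.16), Rrm2 (-2.27) and Acta1 (-1.85). Of 29 S phase genes 18 were lower, and of 21 dissociation stress genes 9 were higher, Hspa1a (3.52) and Socs3 (3.10) among them, and 1 lower. In S1, cluster 0 and atrial-like cells held 4 and 0 UMIs of Hspa1a and 3 and 1 of Socs3, so these sizes rest mostly on S5. Shox2 stood at 2.27, Isl1 had 219 UMIs against 3 (ratio 40.2, 13.6 to 196), and Nkx2-5 (-0.03) and Nppa (-0.30) did not pass. By edgeR 244 of 7984 genes were higher and 250 lower, 488 of these 494 in the same direction in both samples, with 201 by DESeq2 and 71 without the block. Among all cardiomyocytes, cells with UMIs of both Shox2 and Nkx2-5 had more mRNA than cells with Shox2 alone for Acta1 (2.08 ± 0.31), Casq1 (1.46 ± 0.16), Myl3 (1.46 ± 0.25), Kcna5 (1.37), Vcan (1.19) and Nr2f2 (0.99). They had less for Tbx18 (-3.14), Sema3c (-2.14 ± 0.32), Gfra2 (-1.65), Sfrp1 (-1.59 ± 0.15), Nrp1 (-1.53), Tgfb2 (-1.20) and Bmp4 (-1.07), with 122 of 8822 genes higher and 203 lower by edgeR, 323 of these 325 in the same direction in both samples. The compared groups held 98 S1 and 303 S5 cells with both, and 128 and 399 with Shox2 alone. These groups were also set after thinning, so cells with Shox2 alone may hold Nkx2-5 UMIs in their full counts. In the separate draw thinned to 5420 UMIs, cluster 0 held 43 of 84 S1 and 167 of 294 S5 cells with both genes. The contrast is therefore not separate from that of cluster 0 with SAN-like cells. DESeq2 called 71, and edgeR without the block 0, with 466 at an unadjusted p under 0.05.

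Cluster 0 was weighed as doublets of a SAN-like and an atrial-like cell, since it carries the markers of both. Its median UMI number was at most 0.893 times the mean of both classes' medians (0.803 in S1, 0.893 in S5), where a doublet would hold the UMIs of 2 cells, which argues against them as the whole cluster. The other test, written before its result was seen, gave 29 of 6340 genes outside the clustering features, 0.457%, higher in the cluster than in each class, which is under the bound of 1% set for doublets. A simulated mixture gave 0 such genes, but it was the mean of both class profiles with counting noise only. It could hardly exceed both, and it lacks the spread of real sums. Sema3a (2.43 ± 0.24 over SAN-like and 2.40 ± 0.30 over atrial-like cells) ranked first among the genes above both. It was picked from a cluster cut by expression from the same cells. This test therefore does not decide for or against doublets. Some doublets may remain in it; no biological explanation was tested, as the samples form 1 group.

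Cluster 6, led by Cxcl13, Sfrp2, Dcn and Postn, held 61 S1 and 4 S5 cells and may be doublets of a cardiomyocyte and a mesenchymal cell. Its S1 median of 9558 UMIs was 1.55 times the 6158 of other S1 cardiomyocytes. After thinning, 14.0% of its S1 cells (8 of 57, exact 95% interval 6.26% to 25.8%) held both Xist and Y-linked UMIs, beside 3.40% (9 of 265, 1.56% to 6.35%) of other S1 cardiomyocytes, as doublets of embryos of different sex would give; this test was written before its result was seen. What stays open is why nearly all of these cells come from S1, which with 1 library per sample was not tested.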
